A study of Mus musculus with 24 samples.

How the data were processed

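Whole-ear RNA of C57BL/6 mice was sequenced from polyA-selected libraries as single-end reads on a HiSeq4000, per the labels' protocols, in 24 samples of 4 groups: wild type and Card14 E138A knock-in at day 5 and at 1 month, 6 samples each. The deposited values are expected counts per Ensembl gene made by the authors with RSEM, per the file headers, not scaled between libraries. Per the submitters' processing notes the tools were RSEM 1.3.0, STAR 2.5.2 and DESeq2 1.14.1 with genome build GRCm38, and the annotation release is not given in the sources used here. The table held 51912 genes in 24 columns, each matched to 1 sample by its name. Of the values, 6.71% were not whole, and all were rounded before use. Gene symbols, coordinates, lengths and GC content came from GENCODE M21 (GRCm38), in which 51633 of the gene identifiers were found and 279 were not.

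Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 17287, libraries were scaled by TMM factors, and 1 coefficient per group was fitted to all 24 libraries with the robust quasi-likelihood pipeline. The contrasts were mutant minus wild type at day 5 and at 1 month, the difference between these (interaction), and wild type at 1 month minus wild type at day 5. Two-sided quasi-likelihood F tests were adjusted by Benjamini-Hochberg, with calls at an adjusted p below 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM with the SD over libraries, and log2 CPM used a prior count of 2. For a gene with no count in a group the bound was taken against 3 counts over the group, and with 1 to 3 counts the ratio has a 95% counting interval, which covers counting error only.

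The 43 gene lists of pathways and cell types were fixed from textbook knowledge, and were tested with fry of limma 3.58.1 on log2 CPM, adjusted over the lists. Fry asks whether the members of a list move, on balance, 1 way, and does not compare them with other genes. Camera with an estimated correlation between genes, run beside it, does. A call lost there may reflect either difference. List medians take genes without a count in a group at their bound. Named genes were Card14, the 10 largest rises and falls with an adjusted p below 0.05 and a mean of at least 5 CPM in at least 1 of the groups compared (5 each way for the interaction and the wild-type time comparison), and up to 4 members of each described list with the smallest adjusted p. A few genes that this rule names are not reported here. The groups, tests, lists, named-gene rule and the first set of alternative settings were set before the data were examined. Which of the lists the text describes, and how many members of each it names, were chosen after their results were seen.

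The libraries of each group were compared for duplicates by a chi-square over genes with at least 20 counts. The smallest value per degree of freedom was 4.86, so none was counted as a repeat. The replicate numbers of the labels were tested for pairing, and a fit with them as a block was an alternative. The other alternative settings were DESeq2 1.42.0, limma voom with sample quality weights, RLE factors, total counts only, no filter, a filter at 1 CPM in 6 libraries, only the libraries compared, a fit that is not robust, an added minimum log2 fold change of 1, camera for the lists, and leaving out each library in turn. A planned sex covariate was not run, since Xist set against Y-linked genes did not part the libraries by sex. In Y-linked genes alone 4 libraries of 1 month, 1 wild-type and 3 mutant, stood apart. The cause, sex or library composition included, stays open. After the data were seen 4 alternatives were added. Some left out these 4 libraries, or 3 with a GC correlation above 0.4, sets that overlap and so are not separate checks. The others used the library GC correlation as a covariate or protein-coding genes only.

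Counts for 17287 genes passing the filter were simulated from the real means, dispersions and library sizes. Changes were seeded in the day 5 mutants, and 17032 genes passed it again. For the day 5 comparison edgeR called 7 of 66 genes changed 1.5-fold, 45 of 67 changed 2-fold and 58 of 66 changed 4-fold in the right direction, and 4 of the unchanged genes. Of 42 random lists of unchanged genes fry called 1 and camera 1, and a list of 15 genes raised 1.5-fold was called by both.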

Results

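Gene expression was measured by polyA RNA sequencing in 24 whole-ear samples of C57BL/6 mice. The knock-in strain carries a stop cassette flanked by lox sites, and tamoxifen, acting through CreERT2, switches on Card14 with the E138A change at its own locus. CARD14 is a scaffold protein of keratinocytes that passes signals to NF-κB, and this psoriasis-associated mutation was described as leaving that signalling constantly on. Wild-type and mutant ears were taken at day 5, counted from the first tamoxifen injection, and at 1 month, with 6 samples in each of the 4 groups. Total counts per library were 15661515 to 16998900 in wild-type and 16803680 to 18852963 in mutant libraries at day 5. At 1 month they were 19255028 to 23904976 in wild-type and 20608274 to 23022149 in mutant libraries. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples.

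Card14 itself (ENSMUSG00000013483, GRCm38 chromosome 11, 119307768 to 119345375) was read in every library. It lay at 34.6 to 54.1 CPM (counts scaled to a library total of 1e6) in wild-type and 35 to 65.3 CPM in mutant ears at day 5, and at 32.8 to 49.9 CPM in wild-type and 9.92 to 25.2 CPM in mutant ears at 1 month. The day 5 means were 45.5 ± 7.67 CPM and 46.2 ± 11.1 CPM (SD, n = 6 per group), a log2 fold change of 0.02 ± 0.19 (SE) that did not pass the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.943). At 1 month Card14 fell in mutants from 40.4 ± 7.07 CPM to 14.3 ± 5.63 CPM, a log2 fold change of -1.49 ± 0.20 (edgeR adjusted p = 1.58e-06), and this genotype difference changed between the times (interaction -1.52 ± 0.28, edgeR adjusted p = 0.000827). Card14 RNA can depend on how many cells lost the stop cassette, so its level does not check the genotype labels. In a principal component analysis the first component held 42% and the second 24.1% of the variance of log2 CPM.

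**Figure D1:**
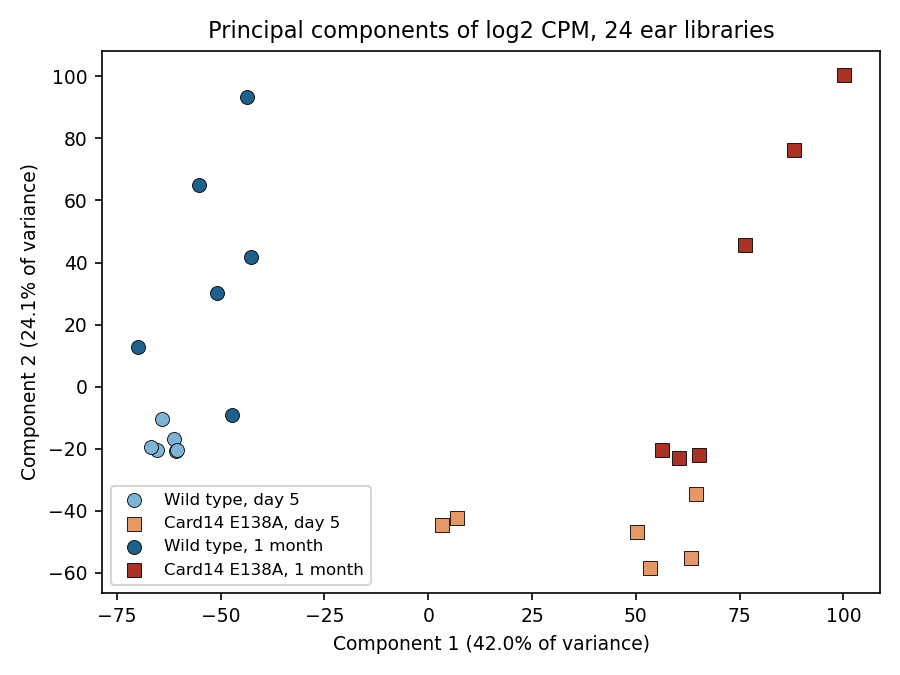
Each point is 1 of the 24 libraries on components 1 and 2 of log2 CPM, with the share of variance on each axis. On component 1 the mutant libraries lie between 3.32 and 100.2 and the wild-type libraries between -70 and -42.7.

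The first comparison asked for the immediate effect of the mutant protein, mutant against wild-type ears at day 5. Most members of the lists of NF-κB targets, the IL-17 axis, antimicrobial peptides, neutrophil chemoattractants and wound keratinocytes were higher in the mutant ears, and most of the melanocyte, cartilage and adipocyte lists were lower. Of all lists, only those of NF-κB targets, the IL-17 axis, chemoattractants, chemokines and the clock kept their call with an estimated correlation. The alarmin genes S100a8 (GRCm38 chromosome 3, 90668978 to 90670035) and S100a9, which code for the subunits of calprotectin, rose from 1.91 ± 0.815 to 1978 ± 1022 CPM and from 2.71 ± 0.638 to 2832 ± 1434 CPM (SD, n = 6), log2 fold changes of 10.01 ± 0.49 and 10.03 ± 0.50 (SE). Il22 (GRCm38 chromosome 10, 118204942 to 118210047), a T-cell cytokine that acts on keratinocytes, had no count in the 6 wild-type libraries and a mean of 16.5 ± 10.1 CPM in mutants, at least 550.3-fold higher against a floor of 3 counts over the group. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3579 genes were higher and 3489 lower in mutants (40.9% of 17287 tested), 1321 and 1310 of them with a log2 fold change of at least 1 in size. The adjusted p of every gene named for day 5 other than Card14 was at most 0.00422, and in 88 of the 94 named genes the 6 mutant libraries did not overlap the 6 wild-type libraries, which follows in large part from choosing genes by this same comparison.

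Of the largest rises at day 5, given here as log2 fold change ± SE with mean CPM in wild type to mutant, several were epidermal or inflammatory genes: Sprr2b, a cornified envelope precursor, 9.90 ± 0.84 (0.119 to 121 CPM), Il19, a cytokine of the IL-10 family, 9.27 ± 0.77 (0.0773 to 53.2 CPM), and the stress keratin gene Krt6b, 9.24 ± 1.06 (2.36 to 1425 CPM). Uox (10.29 ± 0.85, 0.0484 to 70.6 CPM), the gene of urate oxidase, and Fgf23 (9.55 ± 0.68, 0.0495 to 42.3 CPM), the gene of a phosphate-regulating hormone, also rose. The neutrophil chemoattractant gene Cxcl3 had 1 count in the wild-type group and a ratio of 1179 (counting interval 212 to 46558), and Gm5416 had none and was at least 253-fold higher in mutants. The largest falls were in Krtap3-2 (-6.66 ± 0.58, 10.1 to 0.09 CPM), a hair keratin-associated gene, Lce1m (-4.71 ± 0.44, 128 to 4.86 CPM), a late cornified envelope gene, Serpina12 (-4.38 ± 0.36, 118 to 5.66 CPM), which codes for the adipokine vaspin, and Car6 (-4.34 ± 0.48, 6.93 to 0.332 CPM), a secreted carbonic anhydrase gene. Flg2 (-3.81 ± 0.58, 561 to 39.9 CPM) and Flg (-3.15 ± 0.53, 462 to 52.1 CPM), the genes of the filaggrin family that bind keratin in the upper epidermis, fell as well, as did Mrgprb11-ps (-4.15 ± 0.55), Kcnj16 (-3.24 ± 0.38), C1qtnf3 (-3.07 ± 0.31) and Thrsp (-2.87 ± 0.45).

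Lists of inflammatory signalling were called higher to differing degrees, and members are counted here if measured, with medians as log2 fold changes. Of the list of NF-κB and TNF targets, 19 of 19 members rose (19 rose adjusted over the list alone, median 1.54, list adjusted p = 1.04e-11). These included Tnfaip3 (2.58 ± 0.12, 16.5 to 98.2 CPM), the gene of the feedback inhibitor A20, Bcl3 (3.77 ± 0.23, 4.64 to 63.5 CPM) and Birc3 (1.43 ± 0.10, 35.3 to 95 CPM). Of the CARD14 and CBM complex list, 5 of 10 members rose and 5 were not called (5 rose adjusted over the list alone, median 0.35, list adjusted p = 1.56e-05, adjusted p = 0.179 with an estimated correlation). Among them were Bcl10 (0.80 ± 0.13) and Traf3 (0.55 ± 0.10). In the IL-17 and IL-23 list, 13 of 14 members rose and 1 fell (13 rose and 1 fell adjusted over the list alone, median 4.31, list adjusted p = 5.63e-12). Examples were Zc3h12a (3.61 ± 0.17, 23.3 to 284 CPM), the gene of the ribonuclease regnase-1, Ccl20 (6.99 ± 0.47, 0.506 to 65.7 CPM), which attracts CCR6-bearing cells, and Il17f (6.99 ± 0.64, 0.0777 to 11 CPM). In the IL-1 and IL-36 family, 7 of 13 members rose, 1 fell and 5 were not called (7 rose and 1 fell adjusted over the list alone, median 0.50, list adjusted p = 0.000287, adjusted p = 0.330 with an estimated correlation). These included the raised Il1b (7.76 ± 1.06, 0.345 to 77.4 CPM), Il1f6 (3.39 ± 0.45, 4.34 to 45.7 CPM), which codes for IL-36α, and Il1r1 (1.22 ± 0.14, 83.7 to 195 CPM). In the antimicrobial and alarmin list, 12 of 13 members rose and 1 fell (12 rose and 1 fell adjusted over the list alone, median 4.35, list adjusted p = 1.35e-11, adjusted p = 0.0522 with an estimated correlation), and Lcn2 (5.76 ± 0.38, 3.87 to 211 CPM), the gene of an iron-scavenging lipocalin, was among the rises. In the acute phase and complement list, 6 of 8 members rose and 2 were not called (6 rose adjusted over the list alone, median 1.61, list adjusted p = 7.14e-09, adjusted p = 0.0864 with an estimated correlation). Among them were Saa1 (7.78 ± 0.56, 0.0897 to 21.2 CPM) and Saa3 (8.82 ± 0.80, 0.0922 to 43.8 CPM).

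Lists of leukocyte attraction were called higher, and those of leukocyte markers differed in direction. Of the neutrophil chemoattractants, 9 of 9 members rose (9 rose adjusted over the list alone, median 7.09, list adjusted p = 5.07e-11). Examples were Cxcl1 (7.09 ± 0.38, 0.514 to 70.8 CPM), Il6 (7.25 ± 0.63, 0.0403 to 7.06 CPM) and Csf2 (5.14 ± 0.42, 0.0888 to 3.4 CPM). Of the chemokines for monocytes and T cells, 11 of 12 members rose and 1 was not called (11 rose adjusted over the list alone, median 2.62, list adjusted p = 5.63e-12). These included Ccl17 (5.98 ± 0.38, 0.602 to 38.2 CPM), Ccl7 (4.55 ± 0.30, 3.98 to 93.5 CPM) and Ccl22 (2.66 ± 0.16, 5.9 to 37.4 CPM). In the neutrophil marker list, 7 of 8 members rose and 1 fell (7 rose and 1 fell adjusted over the list alone, median 6.03, list adjusted p = 1.75e-08, adjusted p = 0.0924 with an estimated correlation). Among them were Cxcr2 (4.44 ± 0.38, 3.92 to 85.2 CPM), Csf3r (5.07 ± 0.53, 1.82 to 61.6 CPM) and Mmp8 (6.99 ± 0.66, 0.0806 to 11 CPM). In the monocyte and macrophage list, 13 of 14 members rose and 1 was not called (13 rose adjusted over the list alone, median 1.17, list adjusted p = 1.31e-05, adjusted p = 0.179 with an estimated correlation). Examples were Ly6c2 (4.07 ± 0.44), Fcgr1 (3.00 ± 0.36) and Itgam (2.63 ± 0.29). In the dendritic and Langerhans cell list, 3 of 11 members rose and 8 were not called (3 rose adjusted over the list alone, median 0.30, list adjusted p = 0.00167, adjusted p = 0.464 with an estimated correlation). These included Ccr7 (3.24 ± 0.32) and Itgax (1.41 ± 0.14). In the γδ T-cell list, 6 of 8 members fell, 1 rose and 1 was not called (6 fell and 1 rose adjusted over the list alone, median -1.09, list adjusted p = 0.000165, adjusted p = 0.258 with an estimated correlation), and the receptor genes Trdc (-1.44 ± 0.22, 21.3 to 7.85 CPM) and Tcrg-V5 (-1.42 ± 0.30, 2.12 to 0.788 CPM) were among those that fell. The T-cell list was not called (list adjusted p = 0.0935, median -0.18). Here Cd3e (-1.24 ± 0.21) was lower and Icos (1.33 ± 0.30) was higher. It was called lower with only the 12 libraries of day 5 (list adjusted p = 0.000286) and with total counts only (list adjusted p = 0.0276). In the cytotoxic cell list, 2 of 6 members rose, 1 fell and 3 were not called (2 rose and 1 fell adjusted over the list alone, median 0.40, list adjusted p = 0.00223, adjusted p = 0.490 with an estimated correlation). Here Gzma (4.34 ± 0.57) and Gzmb (2.38 ± 0.45) were higher. This list took the opposite sign, uncalled, with only the 12 libraries of day 5 (list adjusted p = 0.270) and with the strict filter (list adjusted p = 0.609).

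The epidermis showed rises of wound and proliferation genes beside falls of some differentiation genes. In the wound keratinocyte list, 12 of 13 members rose and 1 was not called (12 rose adjusted over the list alone, median 3.65, list adjusted p = 1.06e-08, adjusted p = 0.0864 with an estimated correlation). Among them were Krt16 (7.30 ± 0.71, 16 to 2531 CPM), a keratin of activated epidermis, and the stefin genes Stfa1 (8.15 ± 0.69) and Stfa3 (6.92 ± 0.66). In the list of Sprr and Lce3 genes, 17 of 17 members rose (17 rose adjusted over the list alone, median 6.87, list adjusted p = 3.92e-08, adjusted p = 0.0924 with an estimated correlation). An example was Sprr2d (7.57 ± 0.74). In the proliferation list, 16 of 17 members rose and 1 was not called (16 rose adjusted over the list alone, median 1.28, list adjusted p = 1.19e-09, adjusted p = 0.0522 with an estimated correlation). These included Rrm2 (1.69 ± 0.16) and Cdk1 (1.32 ± 0.14). In the granular and cornified layer list, 9 of 19 members fell, 3 rose and 7 were not called (9 fell and 4 rose adjusted over the list alone, median -0.97, list adjusted p = 0.000593, adjusted p = 0.377 with an estimated correlation): Lce1c (-2.23 ± 0.31) was lower, and the suprabasal keratin gene Krt1 (2.94 ± 0.37, 451 to 3456 CPM) was higher. In the basal keratinocyte list, 5 of 10 members fell, 2 rose and 3 were not called (5 fell and 2 rose adjusted over the list alone, median -0.45, list adjusted p = 0.00175, adjusted p = 0.490 with an estimated correlation). Among them were the lowered Krt15 (-2.52 ± 0.28, 1509 to 263 CPM), a keratin of basal and bulge cells, and Lamb3 (-0.84 ± 0.13). The list lost its call with only the 12 libraries of day 5 (list adjusted p = 0.102). In the sebaceous gland list, 9 of 13 members fell and 4 were not called (9 fell adjusted over the list alone, median -0.70, list adjusted p = 0.000244, adjusted p = 0.262 with an estimated correlation). Examples were Scd1 (-1.300 ± 0.17), a fatty acid desaturase gene, and Pparg (-0.96 ± 0.16). The hair follicle list was not called (list adjusted p = 0.558), and Msx2 (-1.35 ± 0.26, 18.2 to 7.11 CPM) was the 1 of its 15 measured members that fell.

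Several lists of the deeper ear tissues were called lower by fry and not by camera. In the cartilage list, 10 of 10 members fell (10 fell adjusted over the list alone, median -1.82, list adjusted p = 8.95e-08, adjusted p = 0.0864 with an estimated correlation). These included Col9a1 (-2.31 ± 0.22, 57.6 to 11.6 CPM) and Col9a3 (-2.11 ± 0.25, 73.2 to 16.9 CPM). In the melanocyte list, 6 of 6 members fell (6 fell adjusted over the list alone, median -1.99, list adjusted p = 1.06e-08, adjusted p = 0.0864 with an estimated correlation). Among them were the pigment enzyme genes Tyrp1 (-2.19 ± 0.22, 22.3 to 4.89 CPM) and Dct (-1.83 ± 0.21, 26.8 to 7.52 CPM). In the adipocyte list, 10 of 11 members fell and 1 was not called (11 fell adjusted over the list alone, median -1.06, list adjusted p = 4.28e-05, adjusted p = 0.184 with an estimated correlation). Examples were Plin1 (-1.54 ± 0.20, 68.9 to 23.7 CPM), a coat protein gene of lipid droplets, and Lpl (-1.20 ± 0.22). In the fibroblast matrix list, 7 of 12 members fell, 1 rose and 4 were not called (8 fell and 1 rose adjusted over the list alone, median -1.18, list adjusted p = 2.86e-06, adjusted p = 0.153 with an estimated correlation). These included Eln (-1.73 ± 0.22, 474 to 143 CPM) and Col5a1 (-1.70 ± 0.24, 443 to 136 CPM). In the skeletal muscle list, 8 of 14 members fell and 6 were not called (13 fell adjusted over the list alone, median -0.95, list adjusted p = 0.0127, adjusted p = 0.464 with an estimated correlation). Among them were Casq1 (-1.44 ± 0.34) and Myh1 (-0.78 ± 0.21). The list of matrix-remodelling genes went the other way: 9 of 12 members rose, 1 fell and 2 were not called (9 rose and 2 fell adjusted over the list alone, median 1.29, list adjusted p = 7.53e-06, adjusted p = 0.179 with an estimated correlation). Examples were Timp1 (3.51 ± 0.41) and Plau (1.17 ± 0.14). Among the mutant libraries of day 5, S100a8 lay at 763 CPM in replicate 1 and 899 CPM in replicate 3, against 2043 to 3504 CPM in the other 4. With limma voom and sample quality weights the day 5 counts were 5693 higher and 6006 lower.

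**Figure D2:**
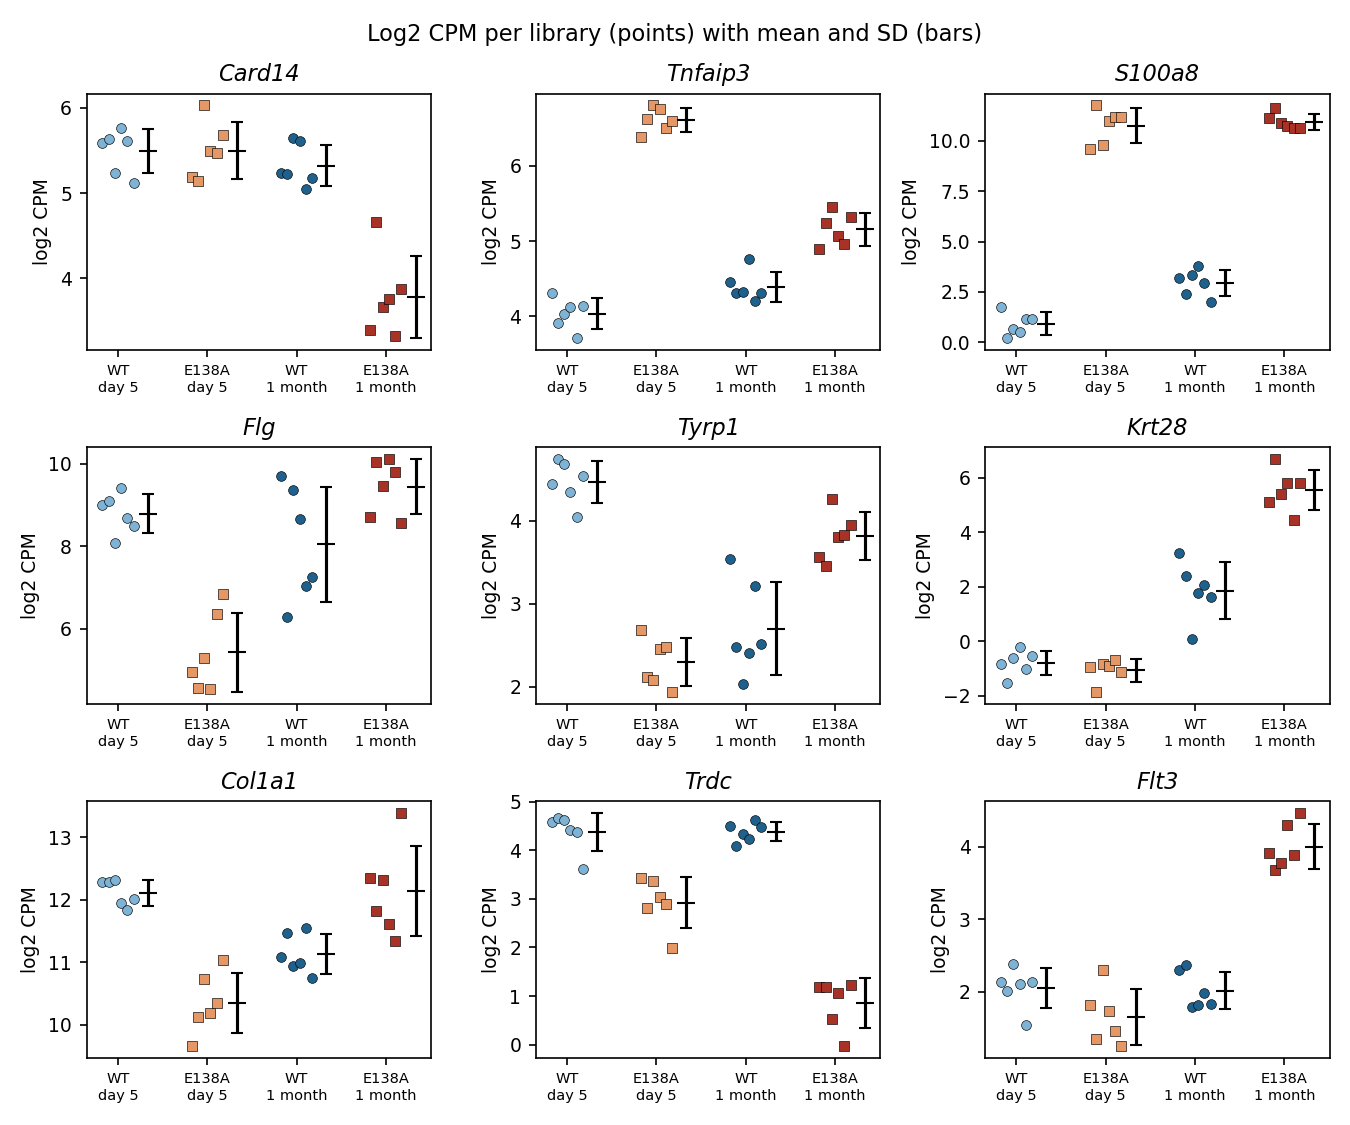
Log2 CPM of 9 genes in each of the 24 libraries, grouped by genotype and time on the horizontal axis, with the group mean and SD as bars beside the points. S100a8 is higher in all 12 mutant libraries than in the 12 wild-type libraries, while Flg, Tyrp1 and Col1a1 are lower in mutants at day 5 and not at 1 month.

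The comparison at 1 month addressed the chronic effect. Many inflammatory and wound genes were higher in mutants. So were 13 of 15 members of the hair follicle list, low and not called at day 5. The 3 measured of the B-cell list, called lower at day 5 (median -0.78, list adjusted p = 0.00862, 0.509 by camera), were higher too. Most members of the muscle, adipocyte, cartilage and γδ T-cell lists were lower, and camera called no list. Chil4, a chitinase-like protein gene, had the largest fitted log2 fold change, rising from 0.555 ± 0.74 to 718 ± 322 CPM (SD, n = 6), a log2 fold change of 10.40 ± 0.75 (SE). S100a8 and S100a9 rose by log2 fold changes of 7.96 ± 0.45 and 7.80 ± 0.45. The largest fall with a count in both groups was in Krt24, a keratin gene of differentiating epidermis, from 206 ± 35.5 to 0.226 ± 0.0586 CPM (-9.80 ± 0.38). By the edgeR quasi-likelihood test 4416 genes were higher and 3723 lower (47.1% of 17287), 1760 and 1813 with a log2 fold change of at least 1 in size. With only the libraries compared in each fit, 3110 genes were higher and 2945 lower at 1 month, against 5093 and 4820 at day 5. Which time had more genes called thus depended on whether the groups shared 1 fit. The Benjamini-Hochberg adjusted p of each gene named for 1 month was at most 0.00424, and 95 of the 99 named genes had no overlap between the 6 mutant and the 6 wild-type libraries, again in large part through the choice of genes.

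Further large rises at 1 month were Uox (8.53 ± 0.71, 0.25 to 92.6 CPM), Sprr2b (8.50 ± 0.78, 0.176 to 62.1 CPM), Sprr2j-ps (7.68 ± 0.79), Ankk1 (7.41 ± 0.49, 0.161 to 28.7 CPM), Serpinb3a (7.19 ± 0.66, 1.78 to 257 CPM), a squamous epithelial protease inhibitor gene, and Stfa3 (7.12 ± 0.65, 7.15 to 991 CPM), and BC117090, a stefin-like gene with 1 count in the wild-type group, had a ratio of 1413 (counting interval 254 to 55804). Stefin, Sprr2, keratin, Saa and chitinase-like genes have near-identical copies, so the split of reads between their members is uncertain. The largest falls included the uncharacterised gene 9130204L05Rik, without a count in the 6 mutant libraries and at least 679.7-fold lower against the floor of 3 counts over the group. Another was Mrgprb3, a G protein-coupled receptor gene with 1 count in mutants, whose wild-type to mutant ratio was 708 (counting interval 127 to 27946). Krt2, the main keratin gene of the upper ear epidermis, fell from 8148 ± 1922 to 67.8 ± 34.1 CPM (-6.91 ± 0.33). Flg2 (-6.82 ± 0.68, 452 to 3.97 CPM), Lce1m (-6.37 ± 0.48, 108 to 1.3 CPM) and Serpina12 (-5.21 ± 0.38, 116 to 3.14 CPM) fell as they had at day 5, together with Mrgprb11-ps (-6.78 ± 0.62), Pyy (-5.90 ± 0.71) and Serpinb6d (-5.47 ± 0.47).

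No list was called by camera at 1 month, so each list count of this time carries its p as well. Of the NF-κB and TNF targets, 16 of 19 members rose and 3 were not called (18 rose adjusted over the list alone, median 1.21, list adjusted p = 7.51e-09, adjusted p = 0.147 with an estimated correlation). These included Bcl3 (3.27 ± 0.23, 5.58 to 53.7 CPM), Nfkbiz (2.21 ± 0.18, 21.7 to 101 CPM), a co-factor gene of IL-17 responses, and Nfkb1 (1.04 ± 0.09, 105 to 215 CPM). Of the CARD14 and CBM complex list, 4 of 10 members rose, 2 fell and 4 were not called (4 rose and 2 fell adjusted over the list alone, median 0.17, list adjusted p = 0.00305, adjusted p = 0.517 with an estimated correlation). Here Card9 (1.08 ± 0.16) and Traf3 (0.63 ± 0.10) were higher and Card14 was lower. The call was lost under scaling by total counts only (list adjusted p = 0.0643). In the IL-17 and IL-23 list, 13 of 14 members rose and 1 fell (13 rose and 1 fell adjusted over the list alone, median 3.05, list adjusted p = 7.51e-09, adjusted p = 0.147 with an estimated correlation). Here Zc3h12a (3.17 ± 0.17, 26.7 to 239 CPM), Il17f (5.73 ± 0.61) and Ccl20 (3.61 ± 0.44) were higher. In the IL-1 and IL-36 family, 8 of 13 members rose, 1 fell and 4 were not called (8 rose and 1 fell adjusted over the list alone, median 0.65, list adjusted p = 3.42e-05, adjusted p = 0.292 with an estimated correlation). Among them were Il1rn (1.57 ± 0.18), Il1f9 (1.96 ± 0.24) and Il1f6 (3.71 ± 0.45). In the antimicrobial and alarmin list, 12 of 13 members rose and 1 fell (12 rose and 1 fell adjusted over the list alone, median 3.63, list adjusted p = 1.06e-09, adjusted p = 0.147 with an estimated correlation). Here Lcn2 (4.77 ± 0.36) was higher and Wfdc21 (-3.19 ± 0.20, 32.9 to 3.6 CPM) was lower. Of the neutrophil chemoattractants, 9 of 9 members rose (9 rose adjusted over the list alone, median 3.82, list adjusted p = 7.15e-08, adjusted p = 0.147 with an estimated correlation). Examples were Cxcl1 (4.35 ± 0.34, 0.646 to 13.4 CPM) and Cxcl5 (5.81 ± 0.70). Of the chemokines for monocytes and T cells, 9 of 12 members rose, 1 fell and 2 were not called (10 rose and 1 fell adjusted over the list alone, median 1.71, list adjusted p = 9.98e-08, adjusted p = 0.147 with an estimated correlation). These included Cxcl16 (1.91 ± 0.16, 29.1 to 109 CPM) and Ccl22 (1.52 ± 0.15).

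Leukocyte markers differed by cell type at 1 month. In the dendritic and Langerhans cell list, 10 of 11 members rose and 1 was not called (10 rose adjusted over the list alone, median 1.22, list adjusted p = 1.85e-08, adjusted p = 0.147 with an estimated correlation). Among them were Flt3 (2.02 ± 0.19), Itgax (1.60 ± 0.14), Ccr7 (2.25 ± 0.28) and the MHC class II gene H2-Aa (1.22 ± 0.19). In the B-cell and plasma cell list, 3 of 3 members rose (3 rose adjusted over the list alone, median 1.75, list adjusted p = 3.15e-06, adjusted p = 0.197 with an estimated correlation). Examples were Igha (3.60 ± 0.50), Cd79b (1.75 ± 0.36) and Ighm (0.66 ± 0.17). In the neutrophil list, 7 of 8 members rose and 1 was not called (7 rose and 1 fell adjusted over the list alone, median 3.28, list adjusted p = 5.18e-06, adjusted p = 0.228 with an estimated correlation). These included Cxcr2 (3.01 ± 0.35) and Csf3r (3.91 ± 0.50). In the monocyte and macrophage list, 14 of 14 members rose (14 rose adjusted over the list alone, median 1.15, list adjusted p = 2.22e-05, adjusted p = 0.228 with an estimated correlation). Among them were Fcgr1 (2.55 ± 0.36) and Adgre1 (0.95 ± 0.18). In the mast cell list, 7 of 10 members rose and 3 were not called (7 rose adjusted over the list alone, median 1.06, list adjusted p = 1.26e-05, adjusted p = 0.228 with an estimated correlation). Examples were Fcer1a (3.21 ± 0.38) and Tpsab1 (2.43 ± 0.28). In the T-cell list, 7 of 15 members rose, 3 fell and 5 were not called (8 rose and 3 fell adjusted over the list alone, median 0.48, list adjusted p = 0.00196, adjusted p = 0.517 with an estimated correlation). Here the helper-cell receptor gene Cd4 (2.19 ± 0.22, 3.28 to 15 CPM) and Icos (2.59 ± 0.28) were higher and Cd3e (-2.09 ± 0.21, 12.4 to 2.91 CPM) was lower. In the γδ T-cell list, 5 of 8 members fell, 2 rose and 1 was not called (5 fell and 2 rose adjusted over the list alone, median -2.58, list adjusted p = 1.85e-08, adjusted p = 0.197 with an estimated correlation). Here Trdc (-3.54 ± 0.25, 20.9 to 1.8 CPM), Tcrg-V5 (-5.31 ± 0.43, 1.77 to 0.037 CPM) and Tcrg-C1 (-3.41 ± 0.34) were lower. In the cytotoxic cell list, 2 of 6 members fell, 2 rose and 2 were not called (2 fell and 2 rose adjusted over the list alone, median -0.05, list adjusted p = 2.79e-05, adjusted p = 0.565 with an estimated correlation). Here Prf1 (-3.62 ± 0.23, 6.77 to 0.545 CPM), the perforin gene, and Nkg7 (-2.01 ± 0.27) were lower.

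In the epidermis and its appendages at 1 month, hair follicle genes joined the rises. In the hair follicle list, 13 of 15 members rose and 2 were not called (13 rose adjusted over the list alone, median 3.48, list adjusted p = 1.48e-06, adjusted p = 0.197 with an estimated correlation). These included the inner root sheath keratin genes Krt28 (3.59 ± 0.39) and Krt73 (3.64 ± 0.42) and the hair cortex keratin gene Krt35 (3.70 ± 0.48). In the wound keratinocyte list, 12 of 13 members rose and 1 was not called (12 rose and 1 fell adjusted over the list alone, median 4.35, list adjusted p = 7.51e-09, adjusted p = 0.147 by camera). Among them were Gjb2 (4.35 ± 0.43), a gap junction gene, Stfa1 (6.75 ± 0.60) and Areg (3.64 ± 0.33). In the Sprr and Lce3 list, 17 of 17 members rose (17 rose adjusted over the list alone, median 5.23, list adjusted p = 2.31e-08, adjusted p = 0.147 by camera). An example was Sprr2i (6.85 ± 0.69). In the proliferation list, 17 of 17 members rose (17 rose adjusted over the list alone, median 1.76, list adjusted p = 4.15e-11, adjusted p = 0.147 with an estimated correlation). These included Plk1 (2.24 ± 0.17) and Rrm2 (2.04 ± 0.16). In the granular and cornified layer list, 12 of 19 members fell, 4 rose and 3 were not called (12 fell and 4 rose adjusted over the list alone, median -2.13, list adjusted p = 9.12e-06, adjusted p = 0.372 with an estimated correlation). Here Flg2 (-6.82 ± 0.68) was lower and Tgm3 (2.07 ± 0.20), an epidermal transglutaminase gene, was higher. In the basal keratinocyte list, 6 of 10 members fell, 3 rose and 1 was not called (6 fell and 3 rose adjusted over the list alone, median -0.57, list adjusted p = 7.02e-05, adjusted p = 0.372 with an estimated correlation). Here Krt15 (-3.24 ± 0.29) and Col17a1 (-1.36 ± 0.14) were lower and Krt14 (1.27 ± 0.19, 4269 to 10262 CPM) was higher. In the sebaceous gland list, 9 of 13 members fell and 4 were not called (9 fell adjusted over the list alone, median -0.86, list adjusted p = 6.23e-05, adjusted p = 0.263 with an estimated correlation). Among them were Scd1 (-1.40 ± 0.17) and Cidea (-1.37 ± 0.23).

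Acute phase and sterol synthesis genes gave weaker list calls at 1 month. In the acute phase and complement list, 4 of 8 members rose, 1 fell and 3 were not called (4 rose and 1 fell adjusted over the list alone, median 0.36, list adjusted p = 0.0264, adjusted p = 0.590 with an estimated correlation). Here Saa3 (5.64 ± 0.65, 0.37 to 18.5 CPM) was higher and Orm1 (-1.31 ± 0.17) was lower. In the sterol synthesis list, 5 of 14 members rose, 2 fell and 7 were not called (5 rose and 2 fell adjusted over the list alone, median 0.25, list adjusted p = 0.0170, adjusted p = 0.590 with an estimated correlation). An example was Sqle (0.87 ± 0.14). The acute phase call was lost on leaving out any 1 of 7 libraries of 1 month (list adjusted p from 0.0543 to 0.458). Without 4 libraries of 1 month set apart by Y-linked genes it took the opposite sign, uncalled (list adjusted p = 0.793), and the T-cell and CARD14 complex calls were lost (list adjusted p = 0.178 and 0.257). The sterol call was lost on leaving out any 1 of 4 (list adjusted p from 0.0567 to 0.0670).

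Among the deeper tissues, muscle, fat and cartilage genes were lower at 1 month. In the skeletal muscle list, 14 of 14 members fell (14 fell adjusted over the list alone, median -2.41, list adjusted p = 1.37e-06, adjusted p = 0.197 with an estimated correlation). These included Casq1 (-2.92 ± 0.36), a calcium store protein gene, and Myh1 (-1.59 ± 0.21). In the adipocyte list, 11 of 11 members fell (11 fell adjusted over the list alone, median -1.78, list adjusted p = 1.55e-07, adjusted p = 0.147 with an estimated correlation). Among them were Plin4 (-1.78 ± 0.18) and Plin1 (-1.82 ± 0.21). In the cartilage list, 9 of 10 members fell and 1 was not called (9 fell adjusted over the list alone, median -1.61, list adjusted p = 3.33e-07, adjusted p = 0.147 with an estimated correlation). Examples were Acan (-1.82 ± 0.21), the aggrecan gene, and Col9a1 (-1.97 ± 0.21). In the melanocyte list, 3 of 6 members rose and 3 were not called (5 rose adjusted over the list alone, median 0.73, list adjusted p = 0.000544, adjusted p = 0.366 with an estimated correlation). These included Tyrp1 (1.05 ± 0.21) and Slc45a2 (1.33 ± 0.37). In the list of matrix-remodelling genes, 9 of 12 members rose and 3 were not called (9 rose adjusted over the list alone, median 1.42, list adjusted p = 1.26e-05, adjusted p = 0.217 with an estimated correlation). Among them were Tnc (2.88 ± 0.32), the tenascin C gene, and Timp1 (2.44 ± 0.38). In the fibroblast matrix list, 7 of 12 members rose, 2 fell and 3 were not called (7 rose and 2 fell adjusted over the list alone, median 0.61, list adjusted p = 0.0270, adjusted p = 0.580 with an estimated correlation). Here Col3a1 (1.304 ± 0.24) and Col1a1 (1.15 ± 0.27) were higher. This fibroblast call was lost on leaving out any 1 of 5 libraries (list adjusted p from 0.0601 to 0.103). The correlation of centred log2 CPM with gene GC content ran from -0.42 to 0.54 across the wild-type and from -0.46 to 0.56 across the mutant libraries of 1 month.

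**Figure D3:**
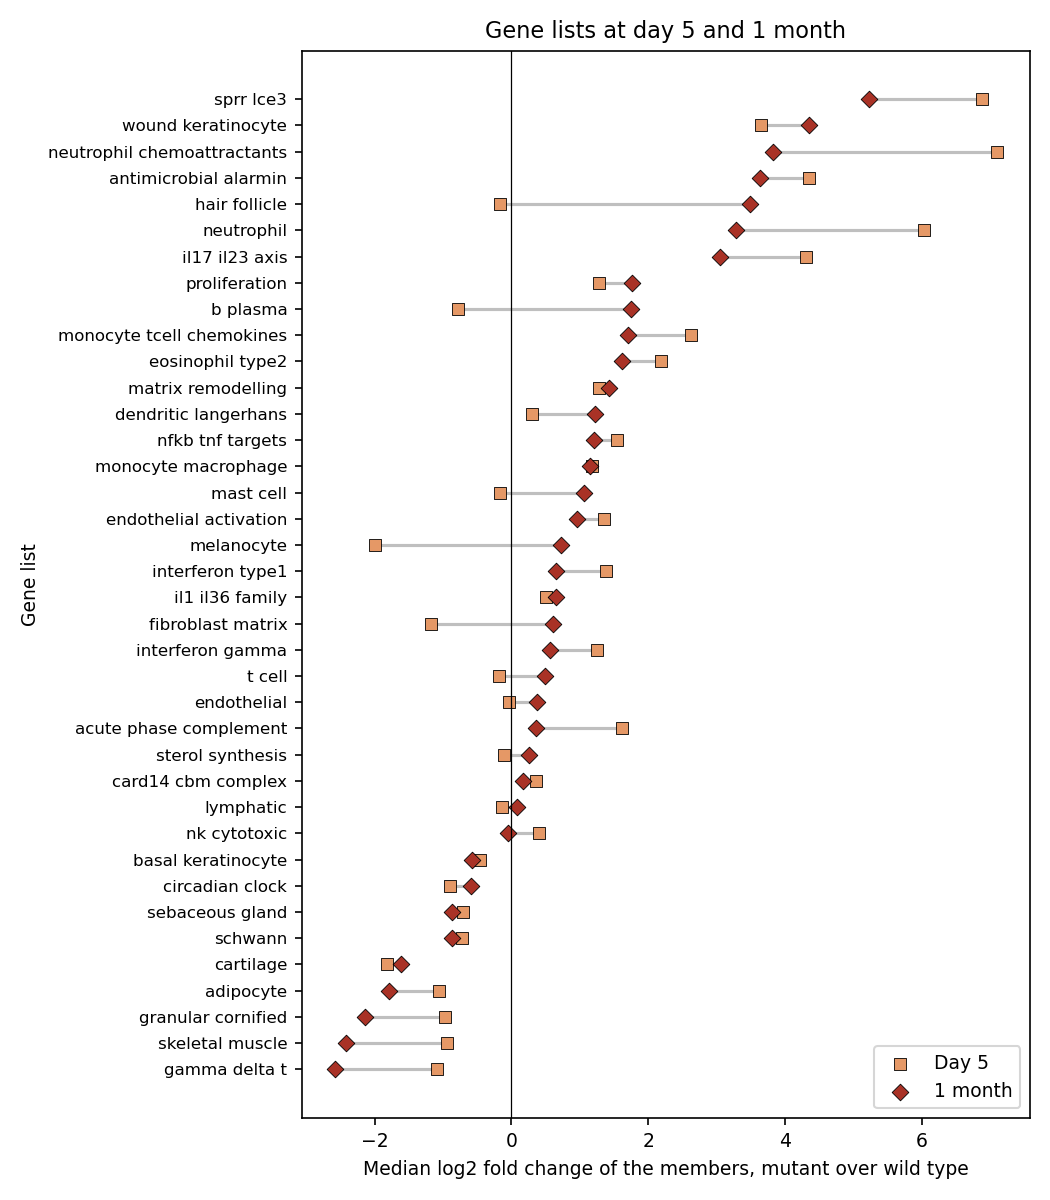
Median log2 fold change of the members of each described list (horizontal axis, mutant over wild type) at day 5 (squares) and 1 month (diamonds), joined by a line. The melanocyte, fibroblast matrix, B-cell, hair follicle, mast cell, T-cell, sterol synthesis, endothelial and lymphatic lists lie below 0 at day 5 and above 0 at 1 month, and the cytotoxic cell list goes from above to below 0.

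The 2 genotype comparisons, which used different wild-type samples, shared much of their gene set. Genes called in the same direction at both times numbered 5152, of which 2852 were higher and 2300 lower, against 914 and 751 for independent lists of these sizes, and 185 were called in opposite directions. Across the 17287 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.73.

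**Figure D4:**
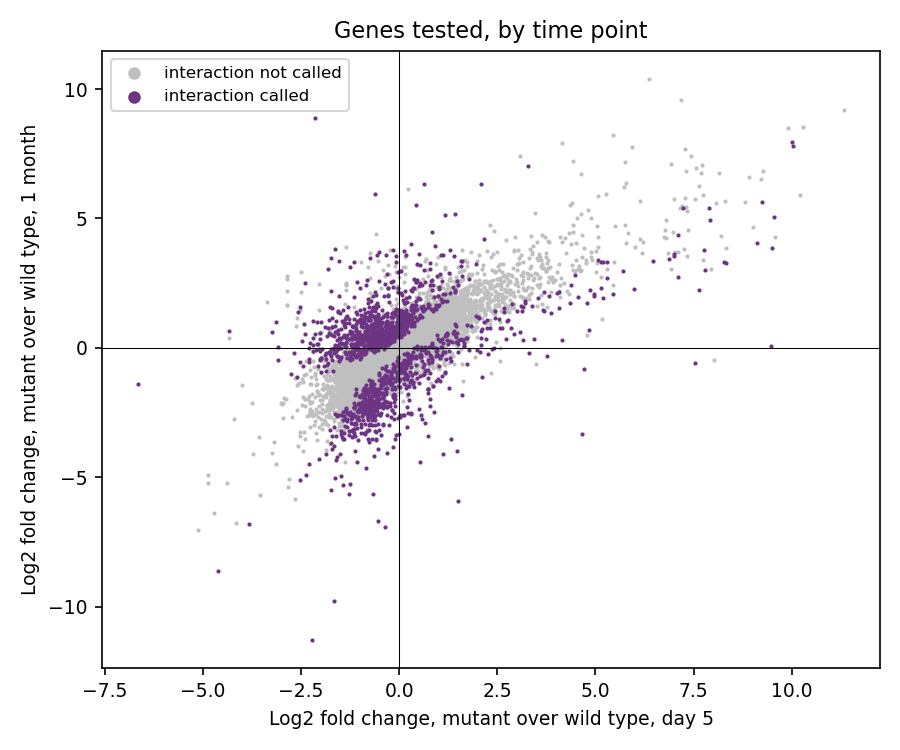
Log2 fold change of each tested gene at day 5 (horizontal) and at 1 month (vertical), mutant over wild type, with genes whose interaction was called drawn in purple. Pearson's r across the 17287 genes was 0.73.

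Whether the genotype difference itself changed between day 5 and 1 month was tested as an interaction, in which a positive log2 value means a difference more positive at 1 month. Members of the hair follicle, melanocyte and fibroblast matrix lists had positive interactions, and Tnfaip3, Nfkbia and members of the chemokine and acute phase lists had negative ones. Tyrp1 went from 22.3 to 4.89 CPM at day 5 and 6.84 to 14.2 CPM at 1 month (wild type to mutant means, n = 6 per group, interaction 3.24 ± 0.31, SE). Tnfaip3 went from 16.5 to 98.2 CPM at day 5 and 21 to 36 CPM at 1 month (-1.80 ± 0.17). The interaction was called positive in 809 and negative in 707 genes by the edgeR quasi-likelihood test, 1503 of these among the 9870 genes called in at least 1 genotype comparison. The adjusted p of the genes named for it was at most 0.0189.

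The largest positive interactions were those of Krtap3-2 (5.27 ± 0.71) and Krt31 (5.22 ± 1.24), both of the hair shaft, Pitx1 (5.10 ± 0.93), a hindlimb homeobox gene, Car6 (4.99 ± 0.61) and S100a3 (4.91 ± 0.41), a hair cuticle gene, and the largest negative ones those of Krt24 (-8.14 ± 0.44), Krt2 (-6.54 ± 0.40), Pyy (-7.41 ± 0.92), 9130204L05Rik and Gm26377. Gm26377 had no count in wild-type ears at day 5 and means of 4.52 CPM in mutants of day 5, 31.1 CPM in wild type and 32.5 CPM in mutants of 1 month. Krt2 went from 12911 to 10022 CPM at day 5 and 8148 to 67.8 CPM at 1 month. In the melanocyte list, 6 of 6 members rose (6 rose adjusted over the list alone, median 2.76, list adjusted p = 1.01e-07). Examples were Tyr (3.34 ± 0.38) and Dct (2.29 ± 0.28) beside Tyrp1. In the fibroblast matrix list, 8 of 12 members rose and 4 were not called (9 rose adjusted over the list alone, median 1.22, list adjusted p = 2.96e-05). These included Col1a1 (2.86 ± 0.39), Col1a2 (2.49 ± 0.34) and Col5a1 (2.496 ± 0.33). In the hair follicle list, low at day 5, 10 of 15 members rose and 5 were not called (11 rose adjusted over the list alone, median 3.42, list adjusted p = 9.87e-05). Among them were Krt28 (3.92 ± 0.68), Krt73 (3.12 ± 0.74) and Hoxc13 (2.15 ± 0.37). The B-cell and plasma cell list also moved up, where 3 of 3 members rose (3 rose adjusted over the list alone, median 2.53, list adjusted p = 1.55e-05). Examples were Ighm (1.92 ± 0.25) and Cd79b (2.53 ± 0.57). In these list counts rose and fell stand for positive and negative interactions.

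Several inflammatory lists had a negative interaction, with many of their members not called. Of the chemokines for monocytes and T cells, 6 of 12 members fell and 6 were not called (9 fell adjusted over the list alone, median -1.61, list adjusted p = 9.25e-05). These included Ccl17 (-3.72 ± 0.48), Ccl7 (-2.57 ± 0.39) and Ccl2 (-2.64 ± 0.46). Of the NF-κB and TNF targets, 8 of 19 members fell and 11 were not called (9 fell and 1 rose adjusted over the list alone, median -0.50, list adjusted p = 0.00762, adjusted p = 0.271 with an estimated correlation). Among them were Nfkbia (-1.32 ± 0.19), the gene of the inhibitor IκBα, and Sod2 (-1.04 ± 0.16). Of the neutrophil chemoattractants, 4 of 9 members fell and 5 were not called (5 fell adjusted over the list alone, median -2.74, list adjusted p = 0.00662, adjusted p = 0.211 with an estimated correlation). Examples were Cxcl1 (-2.74 ± 0.49) and Csf2 (-2.82 ± 0.70). In the acute phase and complement list, 4 of 8 members fell and 4 were not called (7 fell adjusted over the list alone, median -1.304, list adjusted p = 9.87e-05, adjusted p = 0.0547 with an estimated correlation). These included Saa1 (-4.78 ± 0.80), Hp (-2.499 ± 0.42) and Orm1 (-1.58 ± 0.23). In the cytotoxic cell list, 2 of 6 members fell and 4 were not called (2 fell adjusted over the list alone, median -1.11, list adjusted p = 3.04e-05). Among them were Prf1 (-2.85 ± 0.30) and Nkg7 (-1.48 ± 0.37). In the γδ T-cell list, 4 of 8 members fell, 1 rose and 3 were not called (4 fell and 1 rose adjusted over the list alone, median -1.36, list adjusted p = 0.00570, adjusted p = 0.223 with an estimated correlation). Examples were Tcrg-V5 (-3.88 ± 0.54) and Trdc (-2.10 ± 0.32). In the skeletal muscle list, 3 of 14 members fell and 11 were not called (14 fell adjusted over the list alone, median -1.49, list adjusted p = 0.0159, adjusted p = 0.236 with an estimated correlation). These included Myh2 (-1.90 ± 0.43) and Atp2a1 (-1.96 ± 0.52).

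Positive interactions were called in some members of the dendritic, T-cell and mast cell lists. In the dendritic and Langerhans cell list, 5 of 11 members rose and 6 were not called (5 rose and 1 fell adjusted over the list alone, median 1.08, list adjusted p = 0.00240, adjusted p = 0.174 with an estimated correlation). Among them were Flt3 (2.40 ± 0.27), H2-Aa (1.22 ± 0.27) and H2-Eb1 (1.26 ± 0.29). In the T-cell list, 3 of 15 members rose, 1 fell and 11 were not called (6 rose and 3 fell adjusted over the list alone, median 0.95, list adjusted p = 0.00331, adjusted p = 0.174 with an estimated correlation). Examples were Cd4 (2.04 ± 0.31) and Trac (1.49 ± 0.36). In the mast cell list, 3 of 10 members rose and 7 were not called (5 rose adjusted over the list alone, median 1.10, list adjusted p = 0.00409, adjusted p = 0.174 with an estimated correlation). These included Kit (1.21 ± 0.20) and Tpsab1 (1.63 ± 0.39). The granular and cornified layer list was not called (list adjusted p = 0.288), yet Flg (4.15 ± 0.72) went from 462 to 52.1 CPM at day 5 and 377 to 755 CPM at 1 month, and Casp14 (1.88 ± 0.40), which codes for the filaggrin-processing protease, was positive while Flg2 (-3.01 ± 0.76) was negative. The counts moved to 4037 positive and 4180 negative with limma voom and sample quality weights, and to 1443 and 1389 with the GC correlation of each library as a covariate. Without mutant replicate 1 of day 5 the interaction of 9130204L05Rik was no longer called (edgeR adjusted p = 0.0876), and with a replicate block the negative count was 463. Without the 4 libraries set apart by Y-linked genes the counts were 1697 and 2933.

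Wild-type ears at 1 month and at day 5 were compared to show how far the time points differ without the mutation. Most members of the erythroid and hair follicle lists were higher at 1 month, and most of the melanocyte list lower. Of these list calls only the erythroid one held by camera. Hbb-bs went from 0.743 ± 0.484 to 255 ± 92 CPM (SD, n = 6), a log2 fold change of 8.40 ± 0.85 (SE), with Hbb-bt (8.58 ± 0.76), Hba-a2 (7.59 ± 0.93) and Hba-a1 (5.50 ± 0.49) beside it. The edgeR quasi-likelihood test called 1086 genes higher and 486 lower at 1 month, and the adjusted p of the genes named here was at most 0.0137 apart from Card14 (-0.17 ± 0.19, edgeR adjusted p = 0.576). In 21 of the 25 named genes the groups did not overlap, in large part through the choice of genes.

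In the erythroid list, 5 of 5 members rose (5 rose adjusted over the list alone, median 7.59, list adjusted p = 3.71e-09). In the hair follicle list, 12 of 15 members rose and 3 were not called (13 rose and 1 fell adjusted over the list alone, median 3.81, list adjusted p = 0.000164, adjusted p = 0.176 by camera). Among them were Krt73 (3.77 ± 0.51) and Krt27 (4.29 ± 0.62). In the skeletal muscle list, 13 of 14 members rose and 1 was not called (13 rose adjusted over the list alone, median 1.52, list adjusted p = 0.0117, adjusted p = 0.385 with an estimated correlation). Examples were Tnnt3 (1.77 ± 0.37) and Myl1 (1.61 ± 0.35). In the adipocyte list, 4 of 11 members rose and 7 were not called (8 rose adjusted over the list alone, median 0.66, list adjusted p = 0.0117, adjusted p = 0.385 with an estimated correlation). These included Retn (1.55 ± 0.29) and Adipoq (1.19 ± 0.26). In the melanocyte list, 5 of 6 members fell and 1 was not called (6 fell adjusted over the list alone, median -1.24, list adjusted p = 5.18e-05, adjusted p = 0.176 with an estimated correlation). Among them were Tyrp1 (-1.70 ± 0.22) and Tyr (-1.47 ± 0.26). In the sterol synthesis list, 7 of 14 members fell and 7 were not called (10 fell adjusted over the list alone, median -0.46, list adjusted p = 0.000532, adjusted p = 0.207 with an estimated correlation). An example was Sqle (-0.55 ± 0.14). The wound keratinocyte and antimicrobial lists were not called (list adjusted p = 0.106 and list adjusted p = 0.106), although Krt6b (4.20 ± 0.87), Areg (1.86 ± 0.43), S100a8 (2.10 ± 0.38) and S100a9 (2.07 ± 0.38) rose. Fry also called the T-cell (median 0.48, list adjusted p = 0.00168), acute phase (median 0.94, list adjusted p = 0.0117) and dendritic (median 0.41, list adjusted p = 0.0329) lists higher and the proliferation (median -0.35, list adjusted p = 0.0117) and fibroblast matrix (median -0.52, list adjusted p = 0.0122) lists lower, none of them called with an estimated correlation, and the interaction of each was called too. The dendritic call was lost on leaving out any 1 of 8 libraries, the acute phase call any 1 of 5 and the fibroblast call 1.

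Several of the largest changes were in predicted genes and pseudogenes. Gm26377 and Gm10095 had no count in wild-type ears at day 5 and were at least 1036-fold and at least 561-fold higher at 1 month. Gm28439 had none at 1 month and was at least 11292-fold lower there, and Gm3788, with 2 counts at 1 month, had a day 5 to 1 month ratio of 589.6 (counting interval 163 to 4869). Gm21887 (-6.13 ± 0.73), Mir6236 (-5.76 ± 0.66) and Gm10193 (-5.16 ± 0.29) fell as well. Time, age and any batch that follows the time point cannot be told apart here, and reads shared between pseudogenes and their parent genes make the values of the predicted genes uncertain. The counts depended on single libraries, with 2001 higher and 1025 lower without wild-type replicate 1 of 1 month, and with limma voom and sample quality weights they were 3671 and 4556.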

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

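The tests of explanations in this part were chosen after the results they address were seen, apart from the thinning test and the pseudogene and missing-gene counts, whose values were not known when they were chosen. The tests of long transcripts and of the share of keratinocytes replaced earlier tests whose results had been seen.

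Of 539 values of a named gene within a group, 33 had 1 library far from the other 5 by Dixon's ratio on log2 CPM, where chance gives about 1 in 20, or 26.95. In wild type at day 5 these were Thrsp at 12.8 CPM in replicate 3 (others 5.83 to 7.18), Hbb-bt at 0 CPM in replicate 4 (others 0.116 to 0.131) and Gm21887 at 21.7 CPM in replicate 6 (others 4.23 to 6.41). Krt15 at 1876 CPM in replicate 5 (others 1376 to 1522), Lamb3 at 188 CPM in replicate 5 (others 127 to 146) and Lpl at 319 CPM in replicate 3 (others 194 to 219) followed. Trdc at 12.2 CPM in replicate 6 (others 20.6 to 25.2), Sod2 at 80.4 CPM in replicate 1 (others 83.4 to 84.8) and Hoxc13 at 6.14 CPM in replicate 6 (others 4.84 to 5.24) followed. H2-Aa at 261 CPM in replicate 3 (others 185 to 207), H2-Eb1 at 171 CPM in replicate 3 (others 128 to 139) and Retn at 16.9 CPM in replicate 3 (others 8.5 to 10.5) followed. In mutant at day 5 these were Zc3h12a at 181 CPM in replicate 1 (others 271 to 329), Csf2 at 2.14 CPM in replicate 1 (others 3.27 to 4.11) and Plin1 at 34.9 CPM in replicate 3 (others 19 to 22.9). Krt28 at 0.172 CPM in replicate 2 (others 0.361 to 0.521) followed. In wild type at 1 month these were Gm26377 at 8.32 CPM in replicate 5 (others 27.2 to 52.2), Sqle at 157 CPM in replicate 1 (others 107 to 123) and Lcn2 at 9.64 CPM in replicate 5 (others 3.04 to 4.55). Col17a1 at 1117 CPM in replicate 5 (others 1818 to 2175), Itgax at 11 CPM in replicate 4 (others 8.17 to 8.56) and Prf1 at 9.16 CPM in replicate 5 (others 5.91 to 6.95) followed. Nr1d1 at 154 CPM in replicate 1 (others 210.1 to 244), Trac at 0.704 CPM in replicate 1 (others 1.24 to 1.7) and Per3 at 39.9 CPM in replicate 5 (others 67.9 to 81) followed. In mutant at 1 month these were Orm1 at 57.4 CPM in replicate 2 (others 21.1 to 27.5), Il1f6 at 136 CPM in replicate 2 (others 40 to 52.8) and Cxcr2 at 45.8 CPM in replicate 5 (others 33.7 to 37.4). Nkg7 at 2.08 CPM in replicate 1 (others 0.554 to 0.851), Fcer1a at 10.8 CPM in replicate 1 (others 3.5 to 5.22) and Oas1a at 22 CPM in replicate 1 (others 5.11 to 8.76) followed. Dct at 33.6 CPM in replicate 6 (others 19.4 to 22.8) and Trac at 6.4 CPM in replicate 1 (others 2.45 to 3.36) followed. Of the library measures, the number of genes with a count was 23192 in mutant at day 5 replicate 3 (others 22528 to 22727) and the GC correlation was 0.00543 in wild type at day 5 replicate 5 (others -0.259 to -0.167).

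The genotype difference changed between the times, by the interaction test, in 84 of 165 named genes, a share raised by naming some of them for their interaction, against 8.77% of all genes tested. The positive interaction values (log2) were Krtap3-2 5.27, Krt31 5.22, Pitx1 5.10, Car6 4.99, S100a3 4.91, Krt35 4.20, Flg 4.15, Krt28 3.92, Tyr 3.34, Tyrp1 3.24, Krt73 3.12, Col1a1 2.86. Smaller were Slc45a2 2.85, C1qtnf3 2.60, Igha 2.54, Cd79b 2.53, Col5a1 2.496, Col1a2 2.49, Flt3 2.40, Col3a1 2.38, Dct 2.29, Hoxc13 2.15, Cd4 2.04, Ighm 1.92. Last came Casp14 1.88, Dbp 1.74, Eln 1.70, Tpsab1 1.63, Trac 1.49, Msx2 1.37, H2-Eb1 1.26, H2-Aa 1.22, Kit 1.21, Per3 1.04, Tgm3 0.95, Plk1 0.81. The negative ones were Gm26377 -9.41, 9130204L05Rik -9.06, Krt24 -8.14, Pyy -7.41, Krt2 -6.54, Cxcl3 -5.64, Chil3 -5.06, Saa1 -4.78, Fgf23 -4.50, Mrgprb3 -4.00, Il1b -3.98, Tcrg-V5 -3.88. Then came Serpinb6d -3.75, Ccl17 -3.72, Krt6b -3.60, Mmp8 -3.45, Ccl20 -3.38, Flg2 -3.01, Prf1 -2.85, Csf2 -2.82, Cxcl1 -2.74, Npas2 -2.71, Ccl2 -2.64, Ccl7 -2.57. Nearer 0 were Hp -2.499, Tcrg-C1 -2.26, S100a9 -2.22, Trdc -2.10, S100a8 -2.05, Atp2a1 -1.96, Ly6c2 -1.91, Myh2 -1.90, Tnfaip3 -1.80, Wfdc21 -1.72, Orm1 -1.58, Card14 -1.52. Closest to 0 were Nkg7 -1.48, Il4ra -1.39, Nfkbia -1.32, Plin4 -1.20, Arntl -1.20, Ccl22 -1.14, Sod2 -1.04, Irf1 -0.85, Icam1 -0.74, Il1r1 -0.68, Col17a1 -0.63, Birc3 -0.50. The fitted values of 9130204L05Rik and Gm26377 involve groups without a count and depend on the prior count, so they are no bounds.

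It also changed in 19 of the described lists by fry, with median interaction values of proliferation 0.44, hair follicle 3.42, fibroblast matrix 1.22, endothelial 0.43, melanocyte 2.76, dendritic and Langerhans cells 1.08, T cells 0.95, B and plasma cells 2.53, mast cells 1.10, and, on the negative side, NF-κB and TNF targets -0.50, IL-17 and IL-23 -1.05, acute phase and complement -1.304, neutrophil chemoattractants -2.74, monocyte and T-cell chemokines -1.61, skeletal muscle -1.49, γδ T cells -1.36, cytotoxic cells -1.11, eosinophil and type 2 genes -0.84, type I interferon -0.72. With an estimated correlation the melanocyte, fibroblast matrix, hair follicle, B and plasma cell, cytotoxic cell and monocyte and T-cell chemokine lists alone kept their calls.

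Libraries of 1 month differed in whether GC-rich or GC-poor genes were high, in both genotypes. Depth was argued against, since the range of the GC correlation over the 12 libraries was 1.1 before and 1.1 after thinning all to 1 total. Genotype was argued against too, since the mean differed by -0.0991, mutant minus wild type (exact permutation p = 0.703, n = 6 per group), against ranges of 0.959 and 1.02 inside the groups. A loss of long transcripts through RNA quality or library preparation may contribute and stays open: longer genes moved against the GC correlation in all 5 GC classes in 8 of 12 libraries, short of the 10 set as the bar, where a first test by correlation had favoured it. No biological explanation other than genotype was tested.

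The wild-type time comparison was led by pseudogenes and predicted genes. Pseudogenes made up 26.2% of its 195 calls of at least 4-fold, against 3.78% of all genes tested (Fisher's exact p = 7.77e-29) and 3.61% of such calls between genotypes at day 5, in line with reads shared between parent genes and copies being assigned differently at the 2 times. A library batch that follows the time point may be the source, and 2 genes, Gm28439 and Gm10095, both pseudogenes, had no count in all 12 libraries of 1 time point and at least 5 CPM in both groups of the other. Batch, age and time since tamoxifen cannot be told apart for these or other genes, because each time point is 1 set of libraries.

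Card14 was lower in mutants at 1 month and not at day 5. A smaller share of keratinocytes stays open: of 18 lists of other cells 10 were called higher by fry, most of them of leukocytes, and 6 lower, among them muscle, fat and cartilage, none with an estimated correlation, and basal keratinocyte genes moved apart (Krt14 1.27, Krt5 0.42, Krt15 -3.24). Library composition was argued against, since the log2 fold change was -1.47 ± 0.19 with the GC correlation as a covariate and -1.45 ± 0.23 without the 3 libraries with a GC correlation above 0.4. A lower transcript level per keratinocyte, or fewer cells without the stop cassette, may account for it, and neither was tested.

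Other splits of the same libraries into groups of the same sizes were refitted, 100 per comparison with the real one. For genes at day 5, 1 of 100 splits gave as many calls (7068 in the real split, highest other 1), and for lists, 1 of 100 splits gave as many calls (33 in the real split, highest other 23). For genes at 1 month, 1 of 100 splits gave as many calls (8139 in the real split, highest other 5577), and for lists, 1 of 100 splits gave as many calls (37 in the real split, highest other 27). With genotype shuffled within both times, 2 of 100 splits gave as many interaction genes (1516 in the real split, highest other 4902), 2 of 100 splits gave as many interaction lists (20 in the real split, highest other 31), and 1 of 100 splits gave as many genes called the same way at both times (5152 in the real split, highest other 0). The split with more interaction calls kept the real genotypes at 1 month and mixed those of day 5. For the wild-type times, 1 of 100 splits gave as many calls (1572 in the real split, highest other 0). At 1 month 10 other splits also called many genes, where the remaining splits called at most 2. Of the 10, 6 left at most 8 of the 12 libraries with their genotype, and their sides differed in mean GC correlation by 0.34 or more, against 0.0991 in the real split. A GC difference of that size is not enough for such calls, since 8 further splits had it and called 0 genes, and what sets the 2 kinds of split apart stays open.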

How the results depend on the processing

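Of the alternatives, 4 were chosen after the data were seen. Of 7414 alternative values of named genes 7397 kept their direction and side of the threshold, 11 lost the call, 10 of them under the added minimum log2 fold change of 1, and none reversed. The 6 that changed sign were all of Card14 at day 5, which was not called. Of 2419 alternative values of described lists 2248 were unchanged, 154 lost the call, 83 of them with camera and an estimated correlation and 25 of the interaction of the endothelial list, and 5 gained it. The 3 reversals were of the acute phase list at 1 month without the 4 libraries set apart by Y-linked genes (list adjusted p = 0.793), and of the cytotoxic cell list at day 5, with the strict filter (list adjusted p = 0.609) and with only the libraries compared (list adjusted p = 0.270). The T-cell list at day 5 gained a call, lower, with only the libraries compared (list adjusted p = 0.000286), with total counts only (0.0276) and without mutant replicate 4 of day 5 (0.0480). The antimicrobial list gained one, higher, for the wild-type times with only the libraries compared (0.0145), and the granular list gained an interaction call without mutant replicate 2 of 1 month (list adjusted p = 0.0414).

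Some lists of 1 month lost their call, with these list adjusted p values. The acute phase and complement list lost it on leaving out any 1 of 7 libraries, and with no filter (0.0709), only the libraries compared (0.0571), without the 3 libraries with a GC correlation above 0.4 (0.258). The sterol synthesis list lost it on leaving out any 1 of 4, and with scaling by total counts only (0.108), only the libraries compared (0.0543), without 4 libraries of 1 month set apart by Y-linked genes (0.183). The fibroblast matrix list lost it on leaving out any 1 of 5, with total counts only (0.0795) and only the libraries compared (0.0956). It also did so without the same 3 (0.124) or 4 (0.0683) libraries.

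Counts that moved by over 1.5 times, and r where it moved by over its jackknife error, were these, and the cause was not tested unless stated. With limma voom and sample quality weights there were 5693 genes higher and 6006 lower at day 5, 4037 and 4180 for the interaction, 3671 and 4556 for the wild-type times, and r was 0.648. The added minimum log2 fold change of 1 by its construction left 1321 and 1310 at day 5, 1760 and 1813 at 1 month, 522 positive interactions, 515 and 155 for the wild-type times and 1775 called the same way at both times. Camera with an estimated correlation called 5 lists at day 5, 0 at 1 month and 6 for the interaction, where fry had called 33, 37 and 20. For the interaction, the GC correlation as a covariate gave 1443 positive and 1389 negative genes, the fit without the 3 libraries gave 1085 negative, and the replicate block gave 463 negative. For the wild-type times, DESeq2 gave 1888 higher, only the libraries compared 1755 higher, the fit without the 3 libraries 1745 higher, no filter 266 lower, the replicate block 288 lower, the GC covariate 1126 lower and protein-coding genes 306 lower, the last with fewer genes tested. Without the 4 libraries of 1 month set apart by Y-linked genes there were 1697 positive, 2933 negative interactions, 2125 genes higher, 1043 lower between the wild-type times, and r was 0.663.

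Leaving out 1 library in turn gave 651 to 2001 genes higher and 272 to 1025 lower between the wild-type times. The number higher moved by over 1.5 times without wild-type replicate 1 (2001) or 5 (651) of 1 month. The number lower did so without any of 10 of the 12 libraries: day 5 replicates 1, 2, 3, 4 and 6 (287, 288, 296, 274, 296) and 1-month replicates 1 to 5 (1025, 307, 272, 306, 286). At day 5 leaving out 1 library gave 3089 to 3658 genes higher and 3048 to 3750 lower, at 1 month 4123 to 4406 and 3496 to 4120. The replicate numbers showed no pairing, with correlations of same-numbered libraries from -0.73 to 0.26 after group means were taken out. No scaling moved the median log2 fold change of all genes by over 0.1: at 1 month it was 0.0477 with TMM and -0.0269 with total counts. The simulation changed few genes, which makes the adjustment stricter, so its 7 of 66 calls at 1.5-fold give no miss rate here.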

Other observations

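Clock genes differed between genotypes at both times. In the circadian clock list at day 5, 8 of 13 members fell and 5 were not called (9 fell adjusted over the list alone, median -0.89, list adjusted p = 4.55e-10). These included Dbp (-2.30 ± 0.20, 94 to 19.1 CPM) and Nr1d1 (-1.63 ± 0.16, 248 to 80 CPM), output and repressor genes of the clock, and Ciart (-1.28 ± 0.14). At 1 month 8 of 13 members fell, 1 rose and 4 were not called (8 fell and 1 rose adjusted over the list alone, median -0.59, list adjusted p = 5.31e-10, adjusted p = 0.147 with an estimated correlation). Among them were Npas2 (-2.97 ± 0.17, 13.5 to 1.72 CPM), Arntl (-1.36 ± 0.14, 37.4 to 14.5 CPM), which codes for BMAL1, Cry2 (-1.22 ± 0.11, 112 to 47.9 CPM) and Nr1d1 (-1.79 ± 0.16). The interaction was negative for Npas2 (-2.71 ± 0.22) and Arntl (-1.20 ± 0.19) and positive for Dbp (1.74 ± 0.27) and Per3 (1.04 ± 0.25), and for the list as a whole it was not called (list adjusted p = 0.684), where the median was 0.38, the mean 0.05 and the direction of the test down. The time of day of sampling was not analysed here.

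Members of the interferon, endothelial activation and eosinophil lists were also higher in mutants. In the type I interferon list, 11 of 14 members rose and 3 were not called (11 rose adjusted over the list alone, median 1.39, list adjusted p = 1.11e-07, adjusted p = 0.0864 with an estimated correlation) at day 5. Examples were Zbp1 (2.71 ± 0.30) and Mx1 (2.34 ± 0.24). At 1 month 7 of 14 members rose and 7 were not called (7 rose adjusted over the list alone, median 0.65, list adjusted p = 0.000568, adjusted p = 0.366 with an estimated correlation). These included Zbp1 (2.20 ± 0.30) and Oas1a (2.22 ± 0.36). In the list of interferon-γ genes at day 5, 8 of 9 members rose and 1 was not called (9 rose adjusted over the list alone, median 1.25, list adjusted p = 5.91e-07, adjusted p = 0.106 with an estimated correlation). Among them were Irf1 (1.74 ± 0.17) and Psmb8 (1.63 ± 0.23). For interferon-γ genes at 1 month, 4 of 9 members rose and 5 were not called (4 rose adjusted over the list alone, median 0.56, list adjusted p = 0.000233, adjusted p = 0.366 with an estimated correlation). In the endothelial activation list, 6 of 9 members rose, 1 fell and 2 were not called (6 rose and 1 fell adjusted over the list alone, median 1.35, list adjusted p = 9.27e-08, adjusted p = 0.112 with an estimated correlation) at day 5. Examples were the leukocyte adhesion genes Selp (2.58 ± 0.23), Sele (2.70 ± 0.32) and Icam1 (1.95 ± 0.14). At 1 month 6 of 9 members rose and 3 were not called (6 rose adjusted over the list alone, median 0.96, list adjusted p = 2.31e-08, adjusted p = 0.147 with an estimated correlation). These included Selp (3.23 ± 0.23) and Sele (2.76 ± 0.31). The list of general endothelial genes was not called at day 5 (list adjusted p = 0.831, median -0.03 against an upward direction of the test). At 1 month 5 of 10 members rose and 5 were not called (6 rose adjusted over the list alone, median 0.38, list adjusted p = 0.00123, adjusted p = 0.393 with an estimated correlation), and for the interaction it was called positive (list adjusted p = 0.0491, adjusted p = 0.352 with an estimated correlation). That interaction call was lost on leaving out any 1 of 18 of the 24 libraries (list adjusted p up to 0.157). The lymphatic list was called at neither time (list adjusted p = 0.242 and 0.601), and at day 5 its median was -0.13, its mean 0.15 and the direction of the test up. In the list of eosinophil and type 2 genes, 6 of 7 members rose and 1 was not called (6 rose adjusted over the list alone, median 2.19, list adjusted p = 8.58e-09, adjusted p = 0.0864 with an estimated correlation) at day 5. Among them were Chil3 (9.11 ± 0.65, 0.109 to 64.5 CPM) and Il4ra (3.20 ± 0.30). At 1 month 6 of 7 members rose and 1 was not called (6 rose adjusted over the list alone, median 1.62, list adjusted p = 9.70e-06, adjusted p = 0.217 with an estimated correlation). Examples were Chil3 (4.05 ± 0.53) and Il4ra (1.81 ± 0.28). The mast cell list was not called at day 5 (list adjusted p = 0.717, median -0.16, mean 0.30). Here Hdc (3.09 ± 0.46) and Fcer1a (2.13 ± 0.39) were higher. In the Schwann cell list, 3 of 6 members fell and 3 were not called (3 fell adjusted over the list alone, median -0.71, list adjusted p = 2.36e-05, adjusted p = 0.179 with an estimated correlation) at day 5. At 1 month 4 of 6 members fell and 2 were not called (6 fell adjusted over the list alone, median -0.87, list adjusted p = 2.29e-07, adjusted p = 0.147 with an estimated correlation).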
